A study of Homo sapiens with 28 samples.

How the data were processed

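CTCF and MBD3 ChIP-seq libraries and their inputs were made from HEK293T cells and derived edited cells. Per the labels, CTCF was immunoprecipitated after transfection of control siRNA (siNC2, siNC3) or siRNA against MBD2 or MBD3, with 3 immunoprecipitated and 3 input libraries each. MBD3 was immunoprecipitated from cells without and with IAA, with 1 immunoprecipitated and 1 input library each. Groups were taken from the sample titles. The matching of siMBD2 to siNC2 and of siMBD3 to siNC3 follows the numbers in those names and is not stated in the labels. What GCN4 in the titles stands for is not given in the sources used here.

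Per the submitters' processing notes, the tools were FastQC 0.11.7, Bowtie2 2.3.4, SAMtools 1.9, MACS2 2.1.2 and bedtools 2.25.0, and the genome build was hg19. The deposited files are MACS2 narrowPeak lists of an immunoprecipitation against its input, 1 list per condition. How the authors combined the 3 libraries of a condition is not given in the sources used here, and neither are the calling parameters. The lowest −log10 q in the CTCF lists was 1.30 to 1.34. The deposited values per peak are a fold enrichment (a ratio of immunoprecipitated to background signal at the summit), and −log10 p and −log10 q values, as the authors' peak caller wrote them. The list for MBD3 with IAA held a track line and 0 peaks. No hg19 annotation or sequence was used here, so peaks are given by position, and the planned shares of peaks near transcription start sites and the planned gene lists were not run.

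Peaks on chromosomes 1 to 22, X and Y were kept, lines with identical start and end (several summits of a peak) were collapsed to the summit of highest −log10 q, and peaks sharing at least 1 bp were counted as overlapping. The lists held 6473 lines for siNC2, 14664 for siMBD2, 9096 for siNC3, 10177 for siMBD3 and 445 for MBD3 without IAA before this step. Shares are given with 95% Wilson intervals, and no p-values are given, since a single list per condition leaves no replicates to test. Random placements kept each peak's width and chromosome, drawing positions between the outermost peaks of all lists, 100 times per pair of CTCF lists and 1000 times for the MBD3 peaks. Regions common to lists were found by merging all peaks that overlap. Positions are 1-based.

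The pileup and local background of each peak were solved from the authors' fold, taken as pileup plus 1 over background plus 1, and their −log10 p, taken as a Poisson tail. Solved pileups were within 0.02 of a whole number for 100% of solved peaks in every list with peaks, and 2 siNC3 and 4 siMBD3 peaks of very high −log10 p were left unsolved. The immunoprecipitated fragments were therefore counted without scaling, and the lowest background of a list is its genome-wide level. That level divided by the shortest peak of the list, 147 to 153 bp in the CTCF lists, stands for depth. Depth sets precision here only through the peak calls, since read totals were not analysed here. Background of at least 3 times the lowest was called high. This split, the equal-length merging of lists and the removal of crowded windows from overlaps and counts were chosen after the data were seen, as were the tests so described in the closing section. The other alternatives, the planned comparisons of lists and the rule for named peaks, with its own exclusion of crowded windows, were fixed before the data were examined.

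On simulated data, a partner list planted with 50.0% or 90.0% of the siNC2 peaks returned 50.0% and 90.0% with 0 planted peaks missed. Backgrounds of 2000 simulated peaks were recovered with a largest relative error of 1.32e-05, and pileups that had been scaled to fractions came out whole for 4.10% of 2000 peaks.

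Named peaks lie on chromosomes 1 to 22 and X, and exclude peaks over 10 kb and windows of 100 kb with 10 or more peaks in any list. By authors' fold, they are the 10 strongest knockdown peaks found in neither control, the 10 strongest peaks of the control that are also in the other control and absent from the knockdown, the 5 strongest control peaks present in all 4 lists, and the 15 strongest MBD3 peaks without IAA. Alternatives were reciprocal overlap of 50%, summits within 100 bp, −log10 q of 5 or more, fold of 5 or more, equal list lengths, the other control, every line counted and all sequences. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.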

Results

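Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used in HEK293T cells, an established line derived from human embryonic kidney, to map CTCF after knockdown of MBD2 or MBD3, and to map MBD3 with and without CTCF degradation. CTCF is a zinc finger DNA-binding protein that anchors chromatin loops and insulates domains. MBD2 and MBD3 are methyl-CpG-binding domain family proteins, and each is a subunit of the NuRD nucleosome remodelling and histone deacetylase complex. The series title sets the question as the role of NuRD at CTCF sites. The 28 libraries comprised 14 inputs, 12 CTCF immunoprecipitations and 2 MBD3 immunoprecipitations. CTCF was profiled with 3 libraries each in cells given the control siRNAs named siNC2 and siNC3 and the siRNAs against MBD2 and MBD3, at 100 pmol of siRNA. MBD3 was profiled with 1 library without and 1 library with auxin (IAA). IAA was added for 12 hours, starting 48 hours after transfection, to induce degradation of CTCF carrying an auxin-inducible degron. The peak lists hold no measure of how far MBD2, MBD3 or CTCF was depleted.

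The 6 deposited peak lists, 1 per condition, were compared by position on hg19. Because each condition has a single list for all of its libraries, differences between lists have no replicate check, and the 95% Wilson intervals given below cover counting error only. Read totals per library were not analysed here. On chromosomes 1 to 22, X and Y the CTCF lists held 6355 peaks for siNC2, 14343 for siMBD2, 8836 for siNC3 and 9933 for siMBD3. The median peak was 185 bp wide in siNC2, 206 bp in siMBD2, 199 bp in siNC3 and 196 bp in siMBD3. The authors' median fold enrichment over input was 4.31 in siNC2, 5.13 in siMBD2, 5.48 in siNC3 and 6.10 in siMBD3. These folds and the −log10 q values are each list's own, and are used here to describe, rank or filter peaks within a list, so the same cutoff need not mean the same enrichment in each list. The fold and p of a peak also gave its fragment pileup and the local background it was tested against. The lowest background, which tracks the depth of the immunoprecipitated library, was 3.34 fragments in siNC2, 2.64 in siMBD2, 2.28 in siNC3, 1.95 in siMBD3 and 1.81 in the MBD3 list without IAA.

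Knockdown of MBD2 was compared with siNC2 to ask which CTCF sites differ after siRNA against this subunit. CTCF sites of the control were nearly all kept: 5770 of the 6355 siNC2 peaks overlapped a siMBD2 peak (90.8%, 95% interval 90.1 to 91.5). The siMBD2 list was 2.26 times as long, and 8581 of its 14343 peaks overlapped no siNC2 peak, which left 40.2% shared (39.4 to 41.0). Of these additional peaks, 5708 overlapped no peak of either control. Of the 3822 siNC2 peaks that were also present in siNC3, 3731 were present in siMBD2 (97.6%, 97.1 to 98.1) and 91 were missing.

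The 10 strongest siMBD2 peaks absent from both controls had folds of 9.82 to 11.3 and pileups of 35 to 70 fragments. The first lay on chromosome 6 at 9251114 to 9251311 (fold 11.3, −log10 q 29.1) and the second on chromosome 9 at 71650502 to 71650737 (−log10 q 27.9). Next came peaks on chromosome 7 at 45961822 to 45962045 (fold 10.9), which was also listed in siMBD3, and on chromosome 19 at 43733513 to 43733769 (fold 10.6), which had the highest pileup of the 10, 70 fragments. The peak on chromosome X at 64114508 to 64114880 (fold 9.89) and that on chromosome 6 at 132244606 to 132244797 (fold 9.85) were also present in siMBD3, so that 3 of the 10 were found in both knockdown lists. The 10 strongest siNC2 peaks that were shared with siNC3 and absent from siMBD2 had folds of 5.39 to 8.07 in the siNC2 list. They were led by sites on chromosome 20 at 36686015 to 36686242 (fold 8.07), chromosome 16 at 53544431 to 53544636 (fold 6.91) and chromosome 10 at 9251238 to 9251458 (fold 6.47). Of these 10, 7 were listed in siMBD3. The strongest siNC2 sites present in all 4 lists were on chromosome X at 10087450 to 10087999 (fold 32.9), chromosome 2 at 44706574 to 44706893 (fold 26.1), chromosome 7 at 142912167 to 142912558 (fold 25.9), chromosome 16 at 4303992 to 4304370 (fold 25.9) and chromosome 17 at 32526902 to 32527316 (fold 25.7).

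Retention followed peak strength. In the lowest quartile of siNC2 peaks by −log10 q, 79.3% were found in siMBD2, against 99.3% in the highest quartile. The siMBD2 peaks shared with siNC2 had a median fold of 6.03 and a median −log10 q of 17.5, and the siMBD2 peaks not in siNC2 had 4.70 and 9.25. In the highest quartile of siMBD2 peaks 74.6% were in siNC2, and in the lowest 15.6%. When both lists were reduced to the same number of strongest peaks, the share of siNC2 peaks found in siMBD2 was 61.6%, and with a fold of 5 or more required in both lists the ratio of list lengths was 3.76.

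**Figure D1:**
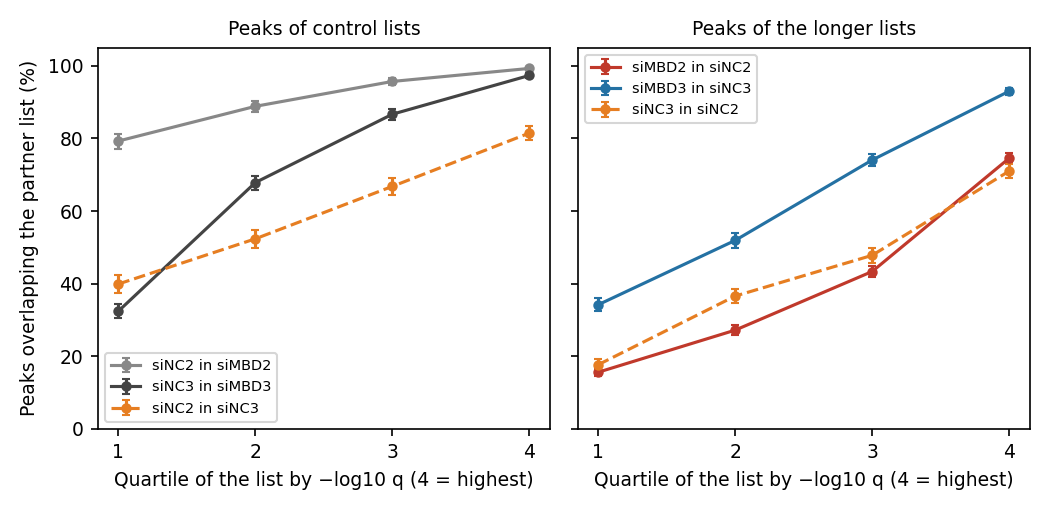
Share of peaks (percent, y axis) that overlapped a peak of the partner list, by quartile of −log10 q within the list asked about (x axis, 4 is the highest), with 95% Wilson intervals; solid lines are control and knockdown pairs, dashed lines the 2 controls. Shares were higher in each successive quartile, from 79.3% to 99.3% for siNC2 peaks in siMBD2 and from 32.4% to 97.4% for siNC3 peaks in siMBD3.

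Knockdown of MBD3 was compared with siNC3. The 2 lists were close in length, with a ratio of 1.12. Of the 8836 siNC3 peaks, 6281 overlapped a siMBD3 peak (71.1%, 70.1 to 72.0) and 2555 did not. Of the 9933 siMBD3 peaks, 6287 overlapped a siNC3 peak (63.3%, 62.3 to 64.2), and 2576 overlapped no peak of either control. Among the 3823 siNC3 peaks that were also in siNC2, 3488 were present in siMBD3 (91.2%, 90.3 to 92.1), and 335 were missing.

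The 10 strongest siMBD3 peaks absent from both controls had folds of 9.89 to 12.8, and 9 of them were also listed in siMBD2. They included sites on chromosome 12 at 31004097 to 31004356 (fold 12.8, −log10 q 31.7), chromosome 2 at 20861261 to 20861511 (fold 12.1), chromosome 17 at 72858422 to 72858654 (fold 11.2), chromosome 14 at 92573036 to 92573252 (fold 10.6) and chromosome 6 at 134242510 to 134242703 (fold 10.6). The exception was a site on chromosome 7 at 130725267 to 130725483 (fold 10.2). The 10 strongest siNC3 peaks that were shared with siNC2 and absent from siMBD3 had folds of 8.22 to 10.0, and all 10 were present in siMBD2. Among them, 2 lay on chromosome 16, at 48387564 to 48387778 (fold 10.0) and 48151434 to 48151666 (fold 8.66), and 2 on chromosome 17, at 26743954 to 26744169 (fold 9.05) and 21023062 to 21023250 (fold 8.95). Of the strongest siNC3 sites present in all 4 lists, 3 lay near the first base of their chromosome: on chromosome 12 at 94081 to 94499 (fold 59.7), chromosome 16 at 60806 to 61218 (fold 58.4) and chromosome 9 at 11237 to 11606 (fold 53.0). The others were on chromosome 2 at 243153684 to 243154090 (fold 56.6) and chromosome 17 at 18528790 to 18529289 (fold 51.4).

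Peaks found in siNC3 and not in siMBD3 were the weaker ones, with a median fold of 4.26 against 6.26 for shared peaks. In the lowest quartile of siNC3 peaks 32.4% were found in siMBD3, against 97.4% in the highest. The siMBD3 peaks not in siNC3 had a median fold of 5.18, and the shared ones 6.86. Some megabases held runs of siNC3 peaks with few counterparts: 45 siNC3 peaks against 6 siMBD3 peaks in megabase 2 to 3 of chromosome 1, 40 against 11 in megabase 36 to 37 of chromosome 19, 49 against 21 in megabase 228 to 229 of chromosome 1, and 35 against 10 in megabase 145 to 146 of chromosome 8. The siMBD3 peaks not in siNC3 were most frequent in megabase 42 to 43 of chromosome 10 (29 siMBD3 peaks against 2), megabase 46 to 47 of chromosome 16 (32 against 6) and megabase 92 to 93 of chromosome 2 (29 against 7).

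The 2 control lists were compared as the background for both knockdowns, and the peaks of each control were found less often in the other control than in either knockdown list. Of the siNC2 peaks, 60.1% (58.9 to 61.3) overlapped a siNC3 peak, below the 90.8% found in siMBD2 and the 71.8% found in siMBD3. Of the siNC3 peaks, 43.3% (42.2 to 44.3) overlapped a siNC2 peak, below the 71.1% found in siMBD3 and the 74.8% found in siMBD2. Both knockdown lists were longer than either control list, with 9933 peaks in siMBD3, and a longer partner list offers more peaks to overlap. These full-length shares therefore do not separate likeness of the lists from partner length. The 40.2% of siMBD2 peaks found in siNC2 cannot be set against these shares either, since siNC2 held 6355 peaks and siMBD2 14343. With the 2 lists of a pair cut to the length of the shorter, the controls shared 52.8% of peaks. At the same length of 6355, 61.6% of siNC2 peaks were in siMBD2 and 61.5% of siMBD2 peaks in siNC2. At the siNC3 length of 8836, 67.9% of siNC3 peaks were in siMBD3. The siNC3 list was 1.39 times as long as the siNC2 list, and 2.63 times with a fold of 5 or more required. Of the 8836 siNC3 peaks, 5013 were not in siNC2. They included 48 of the 49 siNC3 peaks in megabase 228 to 229 of chromosome 1 and all 35 in megabase 145 to 146 of chromosome 8, where siNC2 had no peak. Chromosome 19 held 5.82% of siNC3 peaks and 4.12% of siNC2 peaks, and chromosome 18 held 0.883% and 1.45%. Random placement of the peaks on their own chromosomes gave overlaps of at most 0.407% for any ordered pair of CTCF lists, over 100 placements of each pair.

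**Figure D2:**
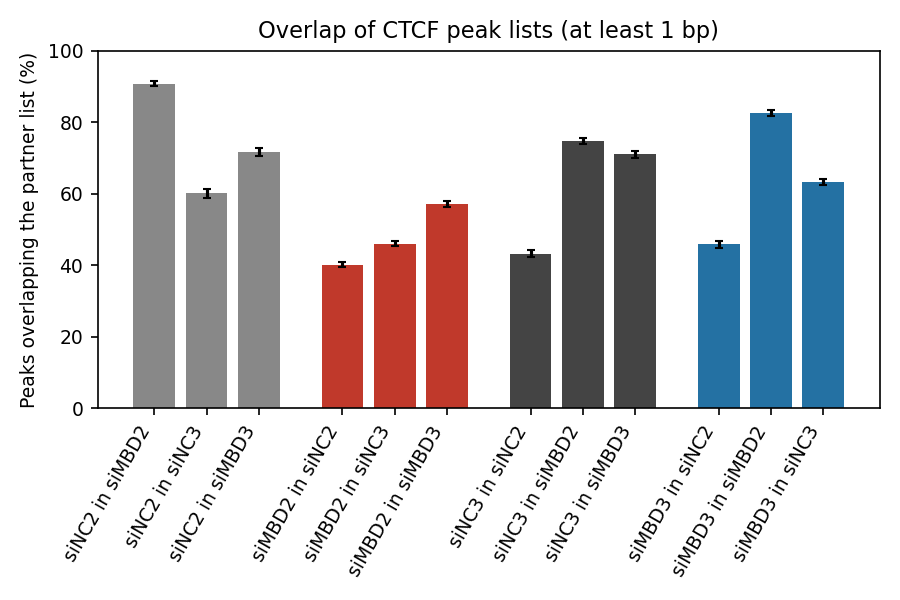
Share of the peaks of each CTCF list (percent, y axis) that overlapped a peak of each other list by at least 1 bp; bars are coloured by the list asked about and error bars are 95% Wilson intervals for counting error. The siNC2 peaks were found in siMBD2 at 90.8% and in siNC3 at 60.1%.

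Merging the 4 CTCF lists gave 18189 regions, of which 3423 were present in all 4 lists. The largest class at full length, 4258 regions, was listed in siMBD2 alone. Regions in both knockdown lists and neither control numbered 1450, and regions in both controls and neither knockdown 23. This contrast depended on list length. With every list reduced to its 6355 strongest peaks by −log10 q, an alternative chosen after seeing the data, the counts were 310 and 229. The regions in siMBD2 alone then numbered 935, fewer than those in siNC2 alone (1426), siNC3 alone (1014) or all 4 lists (2355). At that equal length, 788 regions were shared by siNC2 and siMBD2 alone and 785 by siNC3 and siMBD3 alone, so lists with the same number shared more private regions than lists with the same kind of siRNA. At full length the totals were close: 1052 regions were shared by siNC2 and siMBD2 alone and 434 by siNC3 and siMBD3 alone, 1486 in all, against 1473 for lists with the same kind of siRNA. At equal length the crossed combinations held 308 regions for siMBD2 with siNC3 and 333 for siNC2 with siMBD3, and at full length 518 and 93. The labels do not state that siRNAs of the same number were handled together, and the control of each knockdown was taken from the number in its name.

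**Figure D3:**
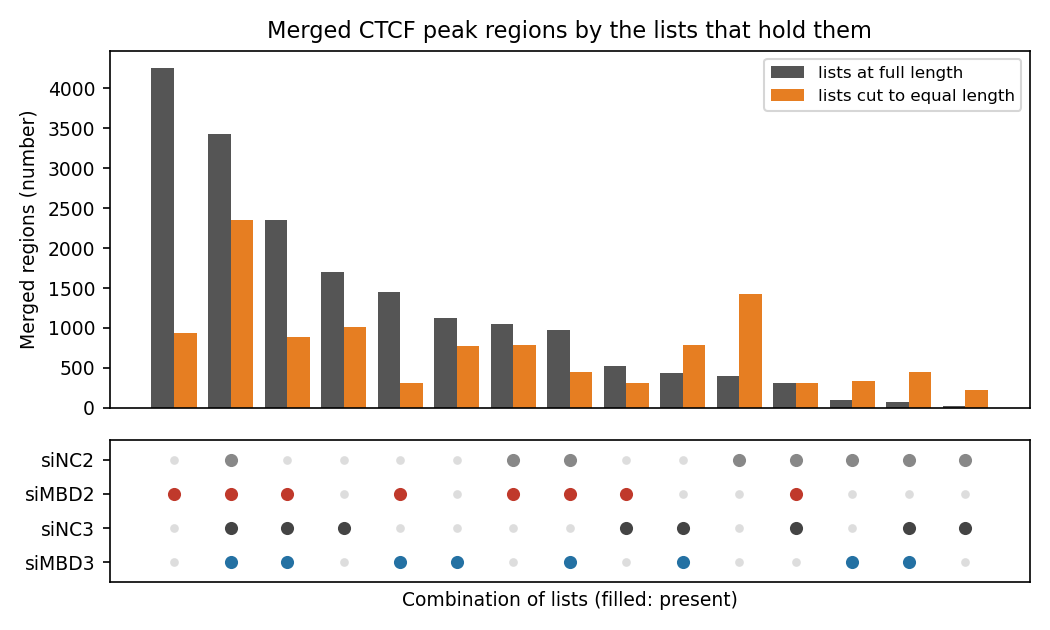
Number of merged CTCF peak regions (y axis) in each combination of lists, which are marked by filled points below the bars; grey bars use the lists at full length and orange bars the 6355 strongest peaks of each list. At full length 1450 regions were in both knockdown lists and neither control, and at equal length 310.

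Peaks were unusually crowded in 24 windows of 100 kb, in 19 blocks, that held 10 or more peaks in at least 1 list. The clearest spacing lay on chromosome X, between summits at 114960606 and 114999416, where the 14 siNC2 peaks followed each other at 13 gaps of 2966 to 3000 bp with a median of 2989 bp. In siMBD2 and siMBD3 the same stretch extended further and held 20 and 21 peaks, with 13 and 12 gaps between 2900 and 3100 bp. The siNC3 list had 44 peaks there at a median gap of 1001 bp. They included a summit close to each of the 14 siNC2 summits, with others between and beyond them. The MBD3 list had 12 peaks there. Median fold over the whole block was 2.13 in siNC2, 3.64 in siMBD2, 4.49 in siNC3 and 10.3 in siMBD3. In the same order, the median local background was 18.8, 15.4, 4.12 and 6.19 times the lowest of each list. Crowded windows held 0.991% of siNC2 peaks, 1.10% of siMBD2 peaks, 3.04% of siNC3 peaks and 2.20% of siMBD3 peaks.

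**Figure D4:**
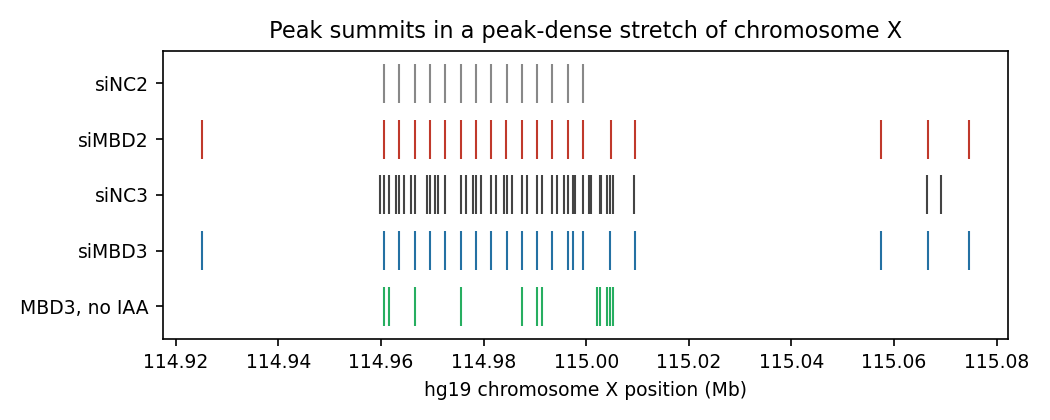
Positions of peak summits (vertical ticks) on hg19 chromosome X (x axis, Mb) in the 4 CTCF lists and in the MBD3 list without IAA, 1 row per list. The 14 siNC2 summits are evenly spaced, at a median of 2989 bp. The 44 siNC3 summits include one close to each of these, with others between and beyond them, at a median gap of 1001 bp.

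MBD3 occupancy was compared between cells without and with IAA to ask whether MBD3 depends on CTCF. Without IAA, 288 MBD3 peaks were listed on chromosomes 1 to 22, X and Y. With IAA, 0 peaks were listed on any sequence. Each condition had 1 immunoprecipitated library and 1 input, and a list without peaks gives no measure of the depth or enrichment of its library, so the difference compares 2 libraries and not replicated conditions.

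The MBD3 peaks without IAA were concentrated in a few places, many of them where the background was high. The 10 megabases with the most peaks held 141 of the 288 (49.0%), and the crowded windows held 137 (47.6%). Megabase 228 to 229 of chromosome 1 held 22 MBD3 peaks, megabase 92 to 93 of chromosome 2 held 20, megabase 61 to 62 of chromosome X held 19 and megabase 46 to 47 of chromosome 16 held 18. The median local background was 32.8 times the list's lowest, against 2.19, 2.12, 1.36 and 1.51 times in the siNC2, siMBD2, siNC3 and siMBD3 lists. Background was at least 3 times the lowest under 187 MBD3 peaks (64.9%), whose median fold was 1.87, and the other 101 had a median fold of 5.19.

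Of the 288 MBD3 peaks, 137 overlapped a CTCF peak of either control (47.6%, 41.9 to 53.3), and none of 1000 random placements on the same chromosomes gave as many, with a highest value of 1.39%. The placements do not keep the crowding of the peaks, and 88 of the overlapping MBD3 peaks lay in crowded windows. Lists that crowd in the same windows would exceed these placements without MBD3 being at CTCF sites. By list, 46 overlapped siNC2 peaks, 113 siNC3 peaks, 124 siMBD2 peaks and 165 siMBD3 peaks, and 66 overlapped no CTCF peak of the 4 lists. The share was 7.64% for CTCF peaks present in both controls. Among the 101 MBD3 peaks of low background, 54 overlapped a siNC3 peak (53.5%, 43.8 to 62.9) and 2 a siNC2 peak (1.98%, 0.545 to 6.93). Of the 65 outside the crowded windows, 19 overlapped a control CTCF peak (29.2%, 19.6 to 41.2). Peaks still clustered outside these windows: megabase 33 to 34 of chromosome 16 held 7 MBD3 peaks, all 7 at a control CTCF peak. The interval takes the 65 peaks as independent. Only 48 siNC2 peaks, 0.755% of that list, and 104 siNC3 peaks, 1.18%, lay at an MBD3 peak. These siNC2 peaks had a median fold of 1.48, against 4.33 for the others, and a median background 55.6 times the list's lowest. CTCF peaks at MBD3 peaks were alike in siMBD2 (fold 1.80, 51.6 times) and siMBD3 (fold 1.91, 57.1 times). In siNC3 their median fold was 4.55, against 5.49 for the others, and the background 3.29 times the lowest, against 1.36.

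Outside the crowded windows, the strongest MBD3 peak was on chromosome 2 at 242512172 to 242512588 (fold 11.4, −log10 q 21.6), where no CTCF list had a peak. The second, on chromosome 2 at 90481672 to 90482273 (fold 9.31), was shared with siNC3 and siMBD3. Next came a peak on chromosome 16 at 33238788 to 33239524 (fold 9.24), which was 1 of 6 among the 15 strongest that lay within megabase 33 to 34 of that chromosome. The fourth was on chromosome 1 at 3392036 to 3392244 (fold 8.53), with no CTCF peak. Of the 15 strongest, 11 were shared with siNC3, 8 with siMBD3 and 1 with siNC2. That 1 peak, on chromosome 12 at 94158 to 94310 (fold 6.75), was present in all 4 CTCF lists, and lay within the strongest siNC3 site on chromosome 12.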

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

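The tests of depth, of the local background of all MBD3 peaks, of the missing MBD3 peaks against CTCF peaks, and of the siNC3 peaks at low-background MBD3 peaks were chosen after the results were seen, as were the comparisons with crossed combinations of lists and of siNC3 with siNC2 at low background, and the share of unshared control peaks above their list's median. The equal-length merging and the limit of 3 times the lowest background, on which other tests rest, were also chosen after the data were seen. Peaks outside chromosomes 1 to 22, X and Y enter the report's comparisons only in the alternative with all sequences, and those given here were listed above the level of the matched control, with exact 95% Poisson intervals that do not meet. The intervals take the peaks of a sequence as independent and do not allow for list length. Un_gl000220 went the other way, with 31 peaks in siNC3 and 21 in siMBD3. The siMBD2 list had 18 peaks on the unplaced sequence Un_gl000226 (10.7 to 28.4), and siNC2 had 3 (0.619 to 8.77), while siMBD3 had 19 and siNC3 7. The siMBD3 list had 31 peaks on 9_gl000199_random (21.1 to 44.0), and siNC3 had 10 (4.80 to 18.4), while siNC2 had 22 and siMBD2 19. The siMBD3 list had 14 peaks on the mitochondrial sequence (7.65 to 23.5), and siNC3 had 0 (up to 3.69), while siMBD2 had 6 and siNC2 2. The MBD3 list without IAA had 25 peaks on 9_gl000199_random, 18 on Un_gl000226, 16 on the mitochondrial sequence and 11 on Un_gl000220, and the list with IAA, which was empty, had 0 on each. Median folds on the mitochondrial sequence were 1.38 in siMBD3 and 1.46 in the MBD3 list.

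The CTCF lists were longer after each knockdown than in the control of the same number, 2.26 times for siMBD2 and 1.12 times for siMBD3. The siNC3 list was 1.39 times as long as the siNC2 list. The MBD3 ratio is therefore smaller than the ratio between the controls, and does not show a lengthening by the knockdown. A deeper immunoprecipitated library would need a higher background per bp of fragment length in the knockdown, and that ratio was 0.786 for siMBD2 over siNC2 and 0.875 for siMBD3 over siNC3, which argues against depth. A higher yield of the immunoprecipitation, which carries weak sites over the calling threshold, was not decided: 34.3% of siMBD2 peaks not in siNC2 and 22.1% of siMBD3 peaks not in siNC3 lay above their list's median −log10 q, but so did only 13.5% of siNC2 peaks not in siMBD2 and 13.8% of siNC3 peaks not in siMBD3, so unshared peaks are weak in either direction. CTCF at more sites in both knockdowns also stays open. At equal list length 57.5% of 539 regions split by kind of siRNA were in the knockdowns (exact binomial interval 53.2 to 61.7, with regions taken as independent). Cutting the lists to 1 length removes any difference in the number of sites before the comparison. The share therefore describes only which of the strongest regions were held in common. The crossed combinations, which no treatment shares, held 641 (611 at full length, against 1473 by kind of siRNA). Lists of the same number shared 1573 (1486 at full length, against 1473 by kind of siRNA). Lists of the same kind of siRNA thus shared fewer regions than crossed lists at equal length, and more at full length. What lists of the same number have in common is not stated in the labels.

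The MBD3 peaks without IAA had a median local background of 32.8 times the list's lowest, a value consistent with reads of many near-identical copies mapped to 1 place for the 187 peaks at 3 times or more. It does not cover the other 101, but a low background does not mark these as single-copy sequence. Megabase 228 to 229 of chromosome 1 held 22 MBD3 peaks at a median background of 1.29 times the lowest, 21 of them at a control CTCF peak. MBD3 at CTCF sites of single-copy sequence stays open. Of the 101 peaks 53.5% overlapped a control CTCF peak, above every random placement (highest 2.97%), but the placements do not keep the crowding of the peaks. Each of these 54 peaks overlapped a siNC3 peak, and 1.98% of the 101 overlapped a siNC2 peak. Outside crowded windows the share was 29.2% (19 of 65, 19.6 to 41.2), an interval that takes the peaks as independent. Clusters remained there: megabase 33 to 34 of chromosome 16 held 7 MBD3 peaks at a median background of 1 times the lowest. All 7 lay at a control CTCF peak, so this share is not free of crowding either. Of the 51 siNC3 peaks at low-background MBD3 peaks, 3.92% were also in siNC2 (1.08 to 13.2), against 43.3% of the whole siNC3 list. Of the 51, 7.84% were in siMBD2, against 74.8% of the whole list, and 56.9% in siMBD3 (43.3 to 69.5), against 71.1%, and 30 of the 101 MBD3 peaks overlapped a siMBD3 peak. Signal common to the siNC3, siMBD3 and MBD3 immunoprecipitations that is not CTCF binding shared by the controls may therefore account for part of the overlap.

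No MBD3 peak was listed with IAA. Loss of MBD3 from CTCF sites is a candidate explanation that predicted fewer than 50% of the missing peaks at no CTCF peak of either control, and 52.4% lay at none (151 of 288). With the knockdown lists included 22.9% lay at none, and 46.5% of the low-background peaks, or 70.8% of those outside crowded windows. The first value is not distinguishable from 50% (47.6% at a control peak, 41.9 to 53.3). Because the list with IAA is empty, the missing peaks are all 288 peaks without IAA, and no value from cells with IAA enters. These shares would be the same whatever emptied that list, so they decide neither way. A shallow or unenriched immunoprecipitated library with IAA could give the same result, and the 0 peaks of that list hold no background from which to test it. These explanations cannot be told apart with 1 library per condition and an empty list. No list maps CTCF in cells with IAA, so the loss of CTCF itself is not shown here.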

How the results depend on the processing

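No paired analysis was possible because each condition has 1 peak list and the lists carry no replicate numbers; leaving out replicates was not possible for the same reason, and shares near transcription start sites and gene lists were not run without an hg19 annotation. The depth of each library is known only through the background of its peaks. Of 83 alternative values, 46 stayed within the main value's interval or within 1.5 times of a count or ratio, and 37 did not. Among the 83, 0 changed direction, but shares and counts have no direction, so this covers only the ratios of list lengths. The 46 include the values for MBD3 with IAA, which an empty list fixed at 0. The cause of the changes was not tested, except that requiring strength or equal length changes which peaks are compared. Removal of crowded windows, the background limit and the equal-length merging were chosen after seeing the data.

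In the order siNC2 in siMBD2, siMBD2 in siNC2, siNC3 in siMBD3, siMBD3 in siNC3, siNC2 in siNC3 and siNC3 in siNC2, a reciprocal overlap of 50% gave shares of 88.6%, 39.2%, 69.7%, 62.0%, 58.4% and 42.0%. In the same order, a −log10 q of 5 or more in the list asked about gave 93.6%, 43.4%, 82.7%, 68.7%, 64.6% and 50.9%, and equal list lengths within each pair gave 61.6%, 61.5%, 67.9%, 67.9%, 52.8% and 52.8%. With a −log10 q of 5 or more in both lists, 38.1% of siMBD2 peaks were in siNC2, 78.3% of siNC3 peaks in siMBD3 and 46.7% of siNC3 peaks in siNC2. With the other control, 74.8% of siNC3 peaks were in siMBD2, 46.1% of siMBD2 peaks in siNC3 and 45.9% of siMBD3 peaks in siNC2. Without crowded windows, 72.1% of siNC3 peaks were in siMBD3. With a fold of 5 or more in both lists, the ratio of list lengths was 3.76 for siMBD2 over siNC2 and 2.63 for siNC3 over siNC2. The siMBD2 and siMBD3 lists stayed longer than their controls under every alternative run, with ratios of 1.62 to 3.76 and 1.11 to 1.56. The siNC3 list likewise stayed longer than the siNC2 list, with ratios of 1.29 to 2.63.

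MBD3 peaks without IAA numbered 178 at a −log10 q of 5 or more, 151 without crowded windows and 101 at low background. The list with IAA was empty before any filter, so its 0 under every alternative run was fixed beforehand. The share of MBD3 peaks at a control CTCF peak was 37.2% by summits within 100 bp, 7.64% for CTCF peaks of both controls, 77.1% for any of the 4 lists, 32.5% without crowded windows and 53.5% at low background. At equal list length, regions in both knockdowns and neither control numbered 310 against 1450 at full length, and regions in both controls and neither knockdown 229 against 23.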

Other observations

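Megabases 60 to 70 of chromosome 13, chosen after seeing where unshared peaks fell, held CTCF peaks that were found less often in the other lists than each list's peaks as a whole, except for siMBD2 peaks in siNC2. The siNC2 list had 34 peaks there, of which 8 were in siMBD2, 4 in siNC3 and 4 in siMBD3. The siNC3 list had 38, of which 8 were in siMBD3 (21.1%, against 71.1% of the whole list). The siMBD3 list had 31, of which 8 were in siNC3 (25.8%, against 63.3%) and 6 in siMBD2 (19.4%, against 82.6%). The siMBD2 list had 20, of which 8 were in siNC2, about the 40.2% of the whole list, 7 in siNC3 (35%, against 46.1%) and 6 in siMBD3 (30%, against 57.2%). The stretch took 19.1% of the chromosome 13 peaks of siNC2, 6.56% in siMBD2, 18.5% in siNC3 and 14.8% in siMBD3. Median fold was 3.35, 4.03, 3.49 and 3.25 in siNC2, siMBD2, siNC3 and siMBD3, in every list below the list's median. Local background was 2.95, 2.52 and 3.17 times the lowest in siMBD2, siNC3 and siMBD3, above list medians of 2.12, 1.36 and 1.51, and 1.61 times in siNC2, below its list median of 2.19.

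Several crowded windows belonged almost to a single CTCF list. On chromosome 19, the window from 36700001 to 36800000 held 32 siNC3 peaks at a median gap of 1172 bp, 3 siMBD3 peaks, and 0 in siNC2 and siMBD2, and the window from 37700001 to 37800000 held 15 siNC3 peaks and 0 in the other CTCF lists. On chromosome 8, 86700001 to 86900000 held 23 siNC3 peaks and 2 siMBD3 peaks. By contrast, on chromosome X the block from 130800001 to 131000000 held 14 siNC2, 23 siMBD2, 16 siNC3 and 22 siMBD3 peaks, and 0 MBD3 peaks. On chromosome 19 the block from 50600001 to 50700000 held 10 siMBD2, 11 siNC3 and 11 siMBD3 peaks at median gaps of 5362, 5340 and 5348 bp, and 3 in siNC2.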
